A study of Mus musculus with 12 samples.

How the data were processed

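Total RNA from mouse hearts was extracted with an RNeasy Mini kit, checked on a Bioanalyzer and labelled as biotinylated cRNA with an Ambion MessageAmp kit for Illumina arrays, per the labels' protocols. The 12 samples form 6 genotype groups of 2, given by the title, source and genotype labels. The scanner and its software are not given in the sources used here. No slide or scan date was used here.

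The main values were the authors' deposited non-normalized intensity values, 1 linear signal for each of 45281 probes and 12 arrays, from 50.1 up to 65008.3. Beside each signal the authors deposited a score headed as a detection p-value. It rises with the signal (rank correlation 0.979 to 0.988) and was therefore used as 1 minus a detection p-value. The authors also deposited processed values on a log2 scale, centred on each probe's median, with array medians of -0.01 to 0.01. Quantile-normalized log2 signals centred in this way differed from them by at most 0.0143 over 8050 bright probes (correlation at least 0.99991), so scale and direction are known from that comparison, and an alternative run on them is nearly the same as one on quantile-normalized signals.

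In R 4.3.3 with limma 3.58.1, the signals were background-corrected and quantile-normalized with neqc (offset 16, negative control behaviour inferred from detection p-values). Probes with a detection p under 0.05 on at least 2 of 12 arrays were kept (22810 probes). Gene symbols came from the platform annotation: 34885 probes had 1 symbol, 18 had several and 10378 had none. Of the probes with 1 symbol, the Entrez ID of 34807 was in the GRCm38.p6 gene table, used for names and for which genes share a chromosome; the files name no genome build, so no coordinates are given. The probe with the highest mean signal stood for each gene, which left 15561 features, 12080 of them with 1 gene symbol; features with several symbols or none are counted and not named.

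Group means were fitted with lmFit and eBayes over all 12 arrays (6 residual degrees of freedom), with 9 contrasts and Benjamini-Hochberg adjusted p under 0.05 as the threshold. A gene detected on 0 arrays of a group has only a bound there. Its fold is given as "at least N-fold": the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest detected signal and the gene's own signal. The smallest detected log2 signal per array was 4.83 to 5.13.

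The 34 gene lists, with 633 members of which 501 were measured, were fixed before the data were examined, as were the contrasts, the tests and the rule for named genes. They hold interferon-stimulated genes, interferon-gamma-inducible GTPases, MHC class I and II presentation, chemokines and cytokines, cytosolic DNA sensing, NF-kappaB targets, complement, cell cycle, cell death, DNA damage response, immediate early genes, contractile, cardiac stress, extracellular matrix, oxidative phosphorylation, fatty acid oxidation, glycolysis and sex-linked genes. They also hold markers of macrophages, T and NK cells, B cells, neutrophils, dendritic cells, mast cells, thymus, fibroblasts, endothelium, smooth muscle, atrium, adipocytes, erythroid cells, skeletal muscle and lung epithelium. Each list was tested with camera (preset inter-gene correlation 0.01, adjusted over the lists within a contrast), with camera at an estimated correlation and with fry. With the estimated correlation, 2 of the 141 list results past the threshold remained past it. Named genes are the targeted genes, the 10 largest rises and falls per contrast among features past the threshold whose arrays do not overlap (for a difference between effects, past the threshold only; predicted genes passed over), and up to 4 members per list past the threshold; where a list had none past it, up to 2 with the highest mean signal.

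The pipeline was tested on simulated data in which 100 genes per size were changed, over 17508 genes. The changed genes were drawn from the brighter features only, and noise was independent between genes. Recovery of dim genes, and false calls from deviations that many genes of an array share, were therefore not tested. For Trex1 KO against WT on STING +/+, 26% of changes of log2 1 and 80% of log2 2 were recovered, with 5 unchanged genes called. For the averaged comparison 1% of changes of log2 0.5 and 46% of log2 1 were recovered, and for the difference between STING +/+ and -/- 1% of log2 1 and 46% of log2 2.

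Alternatives fixed before the data were examined were quantile normalization without background correction, the authors' processed values, no filter and a stricter filter (detection p under 0.01 on at least 4 arrays), a variance trend with a robust prior, array weights, fits of only the groups compared, the probe with the largest variance per gene, an estimated correlation, and leaving out each array in turn. Alternatives added after the data were seen left out 2 arrays with a low Hnrnpa2b1 signal or 2 with raised atrial signal, or used Myl7 or Xist as a covariate. A slide block was not run, since no slide is given in the sources used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.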

Results

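Gene expression was measured in mouse hearts of 6 genotypes, formed by 2 states of Trex1 and 3 states of STING. Trex1 encodes a cytosolic exonuclease that degrades DNA, and STING, encoded by Sting1, is the adaptor through which cytosolic DNA sensed by cGAS induces type I interferon. Hearts were wild type (WT) or deficient (KO) for Trex1, and carried STING as +/+, +/- or -/-. Each genotype was represented by 2 arrays, 12 in all, from untreated mice of mixed C57BL6/129Sv background. The labels do not state that the 2 samples of a genotype came from separate mice. Xist and the Y-linked Eif2s3y, given below, differed in opposite directions between the 2 arrays of Trex1 KO, STING +/+ and of Trex1 WT, STING -/-, which therefore came from mice of different sex. Every p-value rests on a variance per gene pooled over all 6 groups. In the other 4 groups the spread between samples that enters it may be technical. The median probe signal was at most 90.3 per array, and 38.3% to 44.7% of the 45281 probes were detected. The design asks what loss of Trex1 does to heart transcripts, and whether that depends on STING. Differences are given as log2 values ± standard error (SE) from 1 limma fit of all 12 arrays, with Benjamini-Hochberg adjusted p-values; 15561 features were tested. With 2 arrays per group the number of arrays limits the precision.

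The targeted genes were examined first. Probe ILMN_3131766 of Trex1 read 6.53 to 7.34 (log2 signal) on the 6 Trex1 WT arrays and 5.38 to 5.68 on 5 of the 6 Trex1 KO arrays. The array labelled Trex1 KO, STING +/+ replicate 2 read 6.76, within the WT range. Probe ILMN_2509737 behaved alike, with 7.37 to 8.16 on WT arrays, 6.80 to 7.30 on 5 KO arrays and 7.84 on that same array. Another probe, ILMN_2442241, was detected on 0 arrays. Where the probes lie relative to the deleted part of Trex1 is not given in the sources used here, so the signal remaining on KO arrays checks the labels only in part. In Trex1 KO against WT, ILMN_3131766 differed by -0.53 ± 0.34 on STING +/+ (adjusted p = 0.301), -1.56 ± 0.34 on STING +/- (adjusted p = 0.0703) and -1.56 ± 0.34 on STING -/- (adjusted p = 1). ILMN_2509737, the brighter probe, which stood for the gene in the fit, differed by -0.09 ± 0.29 (adjusted p = 0.863), -0.96 ± 0.29 (adjusted p = 0.219) and -0.89 ± 0.29 (adjusted p = 1) in the same comparisons. Every direction below that involves Trex1 KO, STING +/+ takes replicate 2 as labelled, although its Trex1 signal lies within the WT range. The mean of the interferon-stimulated list was 9.97 on that array and 10.45 on replicate 1. It was 6.68 and 7.16 on the Trex1 WT, STING +/+ arrays. That list is also a result below, so it is no separate check of the label. The Sting1 probe ILMN_2736197 read 4.67 to 5.02 on the 4 STING -/- arrays and 4.79 to 5.75 on 6 of the 8 STING-carrying arrays. It was brighter, at 7.03 and 6.94, on the 2 arrays labelled Trex1 KO, STING +/+. The STING genotypes of the groups come from the title, source and genotype labels; the description label gives another STING genotype for 7 of the 12 samples.

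Several arrays stood apart in ways that the genotypes do not account for. Xist, transcribed from the inactive X chromosome in females, read 8.93 to 9.97 on both Trex1 WT, STING +/+ arrays, on replicate 2 of Trex1 KO, STING +/+ and on replicate 1 of Trex1 WT, STING -/-. It read 4.34 to 4.86 on the other 8 arrays. Comparisons that involve Trex1 WT, STING +/+, whose arrays both carried Xist, therefore also compare the sexes in part or in whole. Trex1 KO, STING +/+ and Trex1 WT, STING -/- each held 1 array with Xist and 1 without. Their comparisons with Trex1 KO, STING -/-, whose arrays both lacked it, thus compare the sexes in part. Eif2s3y read 10.1 and 4.35 on replicates 1 and 2 of Trex1 KO, STING +/+, and 4.45 and 10.1 on those of Trex1 WT, STING -/-. The mean of 10 atrial markers was 11.1 and 11.7 on the Trex1 WT, STING -/- arrays, 11.8 on replicate 2 of Trex1 KO, STING -/- and 8.64 on replicate 2 of Trex1 KO, STING +/-, against 6.82 to 7.14 on the other 8. Hnrnpa2b1, an RNA-binding protein gene, read 5.91 on replicate 2 of Trex1 KO, STING +/+ and 8.47 on replicate 1 of Trex1 WT, STING +/-, against 10.9 to 11.6 on the other 10. Mup2, a transcript abundant in liver, read between 7.82 and 12.5 on 5 arrays of 4 groups and at most 5.25 on the other 7. Hnrnpa2b1 and Mup2 were chosen after their values were seen.

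**Figure D1:**
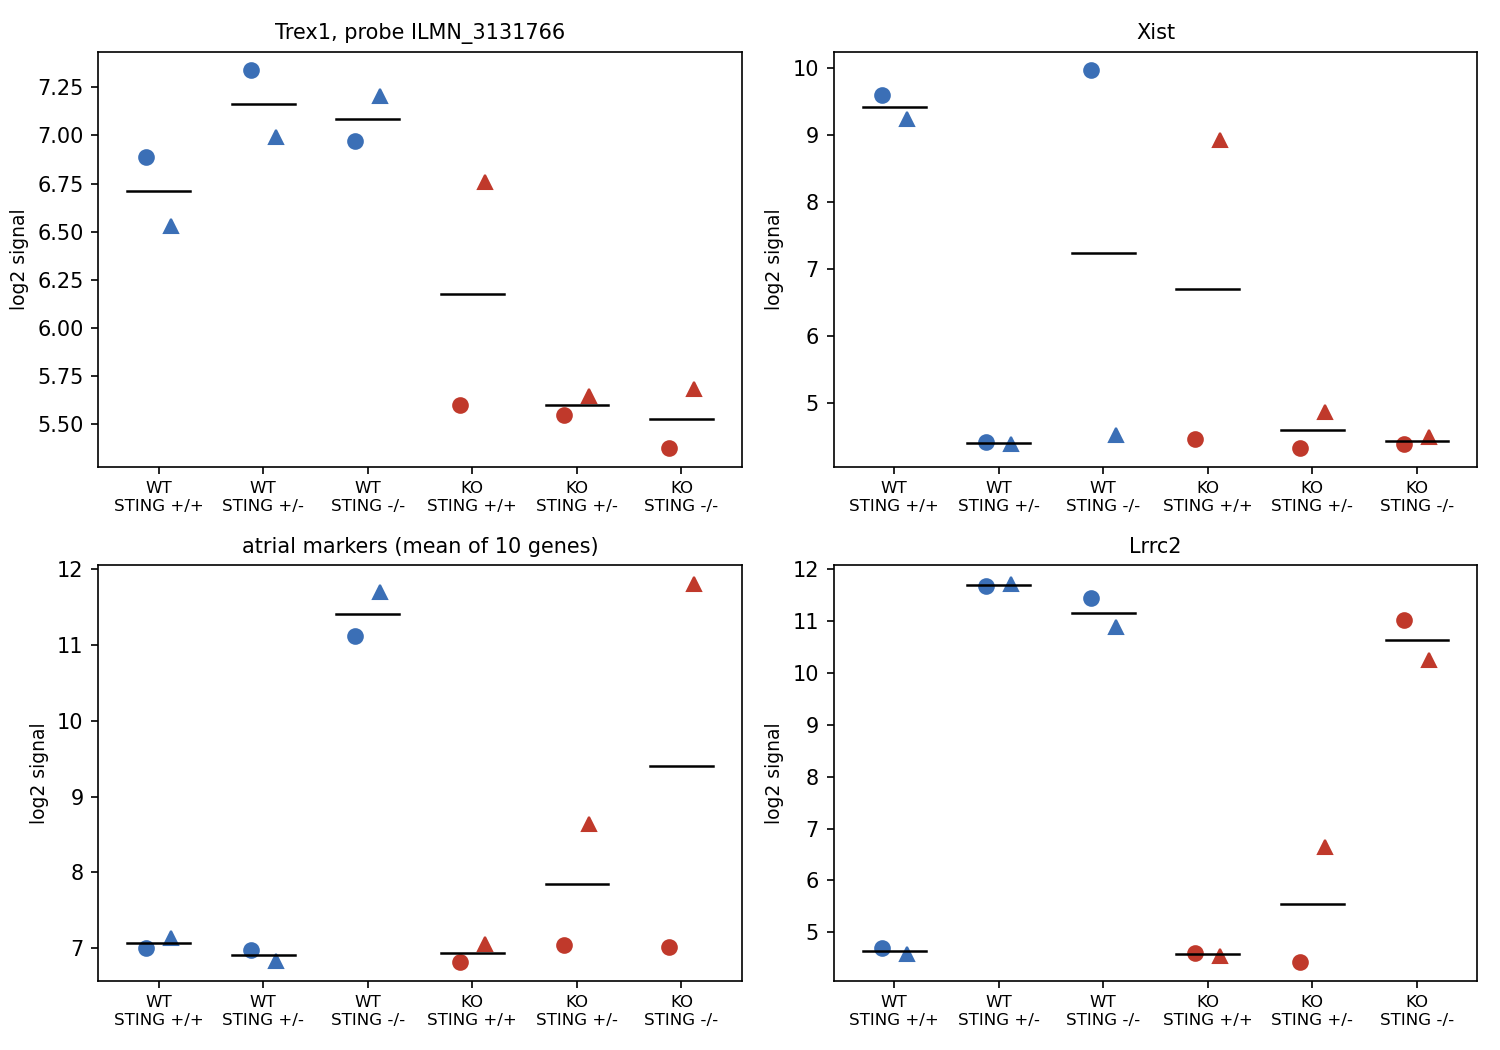
Normalized log2 signal per array (y axis) in the 6 genotype groups (x axis) for Trex1, Xist, the mean of the atrial list and Lrrc2; circles are replicate 1, triangles replicate 2, bars the mean of 2 arrays, blue Trex1 WT and red Trex1 KO. Trex1 on the array labelled Trex1 KO, STING +/+ replicate 2 reads 6.76, and the atrial mean on Trex1 KO, STING -/- reads 7.01 on replicate 1 and 11.8 on replicate 2.

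On STING +/+, 33 of 35 interferon-stimulated genes rose in hearts labelled Trex1 KO and 18 of 27 fatty acid oxidation genes fell. The interferon-stimulated list passed camera's threshold with the preset correlation, at the value given below. With an estimated correlation neither list passed (camera adjusted p = 0.139 and adjusted p = 0.15). Replicate 2 of this group had a Trex1 signal within the WT range. Usp18, which deconjugates ISG15 and dampens interferon signalling, was 68.6-fold higher, and Irf7, a transcription factor that amplifies type I interferon, was 65.5-fold higher. Irf7 was above background on only 1 of the 2 WT arrays, so its fold is not exact. The chemokine Ccl5 was 88.0-fold higher, and Cxcl10 at least 42.9-fold higher over a WT signal not above background. Acaa2, a mitochondrial enzyme of fatty acid β-oxidation, fell by 3.14 on the log2 scale, and Ppara, the transcription factor of fatty acid oxidation genes, fell by 2.50. In total 3378 features passed the threshold, 1833 higher and 1545 lower.

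Of 35 measured interferon-stimulated genes, 33 rose and 0 fell, with a median log2 difference of 3.00, also with members below background at their bound; adjusted over the list alone, 34 rose. Usp18 (6.10 ± 0.36, adjusted p = 1.79e-05), Irf7 (6.03 ± 0.49), Ifit3 (5.98 ± 0.43) and Isg15 (5.81 ± 0.49) rose most. The shift against all other genes had a camera adjusted p = 5.12e-26 with a preset correlation, and adjusted p = 0.139 with an estimated correlation. Interferon-gamma-inducible GTPases, which act against intracellular pathogens, rose in 11 of 13 members (12 adjusted over the list alone), with Igtp at 5.85 ± 0.39 and Gbp2 at 4.22 ± 0.39; adjusted p = 0.15 with an estimated correlation. MHC class I presentation and immunoproteasome genes rose in 16 of 19, among them Psmb9 (4.10 ± 0.33), a catalytic immunoproteasome subunit, and H2-T23 (4.10 ± 0.37); Nlrc5, their transactivator, was at least 13.3-fold higher. The list had adjusted p = 0.139 with an estimated correlation. MHC class II presentation genes rose in all 11 measured members, with H2-DMb1 at 4.86 ± 0.50, Ctss at 4.67 ± 0.37 and H2-Ab1 at 4.32 ± 0.51; adjusted p = 0.15 with an estimated correlation.

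Chemokines and cytokines rose in 19 of 28 members and fell in 2, with a median of 2.35 (2.19 with bounds). Ccl4 (6.81 ± 0.46), Ccl5 (6.46 ± 0.42) and Cxcl9 (5.98 ± 0.38), which attract T cells and monocytes, rose most; adjusted p = 0.139 with an estimated correlation. Of 18 NF-kappaB targets 12 rose and 1 fell, with Cd40 at 3.31 ± 0.27 and the adhesion molecule Icam1 at 2.37 ± 0.35; adjusted p = 0.0954 with an estimated correlation. In the list of cytosolic DNA sensing genes 6 of 19 rose and 2 fell; the DNA sensor Cgas was higher by 2.22 ± 0.29 and the dNTP hydrolase Samhd1 by 2.64 ± 0.25. The list had adjusted p = 0.139 with an estimated correlation. Complement genes rose in 8 of 10, including C2 (4.85 ± 0.83) and C4b (3.61 ± 0.50), and Cfb was at least 32.0-fold higher; adjusted p = 0.15 with an estimated correlation.

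Markers of several leukocytes were higher. Of 20 macrophage and monocyte markers 14 rose and 2 fell, with Lgals3 (6.05 ± 0.99) and Ms4a7 (5.00 ± 0.55) the largest rises, while Cd163, a scavenger receptor of resident macrophages, was at least 10.8-fold lower. T cell and NK cell markers rose in 12 of 17 members: Nkg7, of cytotoxic granules, by 4.98 ± 0.33, and the T cell receptor chains Cd3g and Cd3d by at least 23.2-fold and at least 22.4-fold. Dendritic cell markers rose in 6 of 9, with Bst2 at 3.75 ± 0.37 and Irf8 at 3.03 ± 0.34, and B cell and plasma cell markers in 4 of 7, with Mzb1 at 1.84 ± 0.32. These 4 lists each had adjusted p = 0.15 with an estimated correlation. Neutrophil markers rose in 3 of 7 (camera adjusted p = 0.143). Mast cell markers went both ways, with 1 rise and 3 falls among 6 (camera adjusted p = 0.22): the histamine-forming Hdc was higher by 2.98 ± 0.35 and the protease Cpa3 fell by 1.79 ± 0.40. Bst2 also stands in the interferon-stimulated list.

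Cell cycle genes rose in 15 of 17 members, with the spindle protein gene Nusap1 at 2.78 ± 0.32, the APC/C activator Cdc20 at 2.53 ± 0.39 and Cdk1 at 2.35 ± 0.37; adjusted p = 0.15 with an estimated correlation. Cell death genes rose in 8 of 15, with Casp1 at 3.46 ± 0.31, the necroptosis effector Mlkl at 2.78 ± 0.27 and the pore-forming Gsdmd at 2.06 ± 0.35; adjusted p = 0.15 with an estimated correlation. Of 17 DNA damage and p53 genes 5 rose and 2 fell (camera adjusted p = 0.0916), Cdkn1a being higher by 2.13 ± 0.44.

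Cardiac stress and fetal genes rose in 12 of 16 members with a median of 2.13; adjusted p = 0.0954 with an estimated correlation. Nmrk2, a nicotinamide riboside kinase, rose by 5.34 ± 0.43, Timp1, an inhibitor of matrix proteases, by 4.96 ± 0.50, and Serpina3n, a protease inhibitor, by 4.60 ± 0.69. Extracellular matrix and fibrosis genes rose in 8 of 31 and fell in 1, with the crosslinking enzyme Lox at 2.55 ± 0.40 and Ccn2, listed under its older symbol, at 2.07 ± 0.58; adjusted p = 0.405 with an estimated correlation. Timp1 and Ccn2 stand in both of these lists, and Lgals3 also stands among the cardiac stress genes. Fibroblast markers split into 1 rise and 3 falls among 11 (camera adjusted p = 0.88), the actin-severing Gsn falling by 4.56 ± 1.24; the list's median was 0.17 (0.03 with bounds) and its mean -0.34, and camera's direction was down.

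Fatty acid oxidation and lipid handling genes fell in 18 of 27 members (22 adjusted over the list alone) and rose in 0, with a median of -1.39 (-1.41 with bounds); adjusted p = 0.15 with an estimated correlation. Hadh fell by 2.68 ± 0.42 and Acot1 by 2.09 ± 0.37. Oxidative phosphorylation genes fell in 16 of 27, with a median of -0.81 (-0.82 with bounds), Atp5pb falling by 1.65 ± 0.36, Sdhc by 1.44 ± 0.23 and Uqcrc1 by 1.23 ± 0.21; adjusted p = 0.15 with an estimated correlation. Cardiomyocyte contractile genes fell in 8 of 23, with a median of -0.56. The creatine kinase gene Ckm fell by 1.71 ± 0.23, the calcium release channel Ryr2 by 1.57 ± 0.27 and titin, Ttn, by 1.46 ± 0.19; the list had adjusted p = 0.15 with an estimated correlation. In glycolysis 2 of 15 genes rose and 4 fell (camera adjusted p = 0.531), with a median of 0.14 while camera's direction was down: the insulin-responsive glucose transporter Slc2a4 fell by 2.24 ± 0.25 and the basal transporter Slc2a1 was higher by 1.65 ± 0.25. Smooth muscle and pericyte markers fell in 5 of 11, Abcc9 by 2.39 ± 0.40 and Rgs5 by 2.15 ± 0.48; adjusted p = 0.256 with an estimated correlation. Endothelial markers fell in 3 of 16 (camera adjusted p = 0.125), the angiopoietin receptor Tek by 1.32 ± 0.22. Replicate 2 of Trex1 KO, STING +/+, the array with the low Hnrnpa2b1 signal, gave a median fatty acid oxidation difference from WT of -1.59, and replicate 1 gave -1.06. The contractile median was -0.824 on replicate 2 and -0.235 on replicate 1, and that of oxidative phosphorylation -0.555 and -0.945.

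The remaining lists did not pass camera's threshold on STING +/+ (adjusted p from 0.203 to 0.962). Atrial markers had 1 rise (Nppa, also a cardiac stress gene, 1.47 ± 0.22) and 2 falls among 10, the receptor Gpr22 falling by 3.43 ± 0.28. Adipocyte markers had 1 fall among 8, lipoprotein lipase Lpl, which also stands in the fatty acid list, falling by 1.44 ± 0.40, with a median of -0.06 (0.04 with bounds). Skeletal muscle markers had 1 rise (Myl1, 3.25 ± 0.76) and 1 fall (Ckm, also a contractile gene) among 7, with a median of 0.04 and camera's direction down, and lung epithelial markers 1 rise among 2, the aspartic protease Napsa at 3.44 ± 0.39. Immediate early and dissociation stress genes had 2 rises and 1 fall among 18, Egr2 being higher by 2.46 ± 0.61. Thymus markers (3 measured), erythroid markers (4) and sex-linked genes (4) had 0 members past the threshold, and Xist, raised on both WT arrays and 1 of the 2 KO arrays, differed by -2.72 ± 1.59 (adjusted p = 0.252).

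The largest single rises were Plac8 (7.35 ± 0.55), Ccl4 (6.81 ± 0.46), the Fc receptor Fcgr4 (6.72 ± 0.47) and Cd72 (6.60 ± 0.59), and Apol9a was at least 60.2-fold higher. After Gsn, the largest falls were the carboxylesterase Ces1d (-4.33 ± 0.30), the water channel Aqp1 (-3.68 ± 0.43), Smco1 (-3.64 ± 0.24), the ferritin receptor Scara5 (-3.56 ± 0.25), F13a1 (-3.51 ± 0.38), Timp4 (-3.45 ± 0.52) and Isoc2a (-3.45 ± 0.61). The count of 3378 moved to 1998 with array weights and 1418 with only the 4 arrays compared; leaving out 1 array moved it to 1659 (without WT replicate 1), 1837 (without WT replicate 2) and 5168 (without KO replicate 1).

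**Figure D2:**
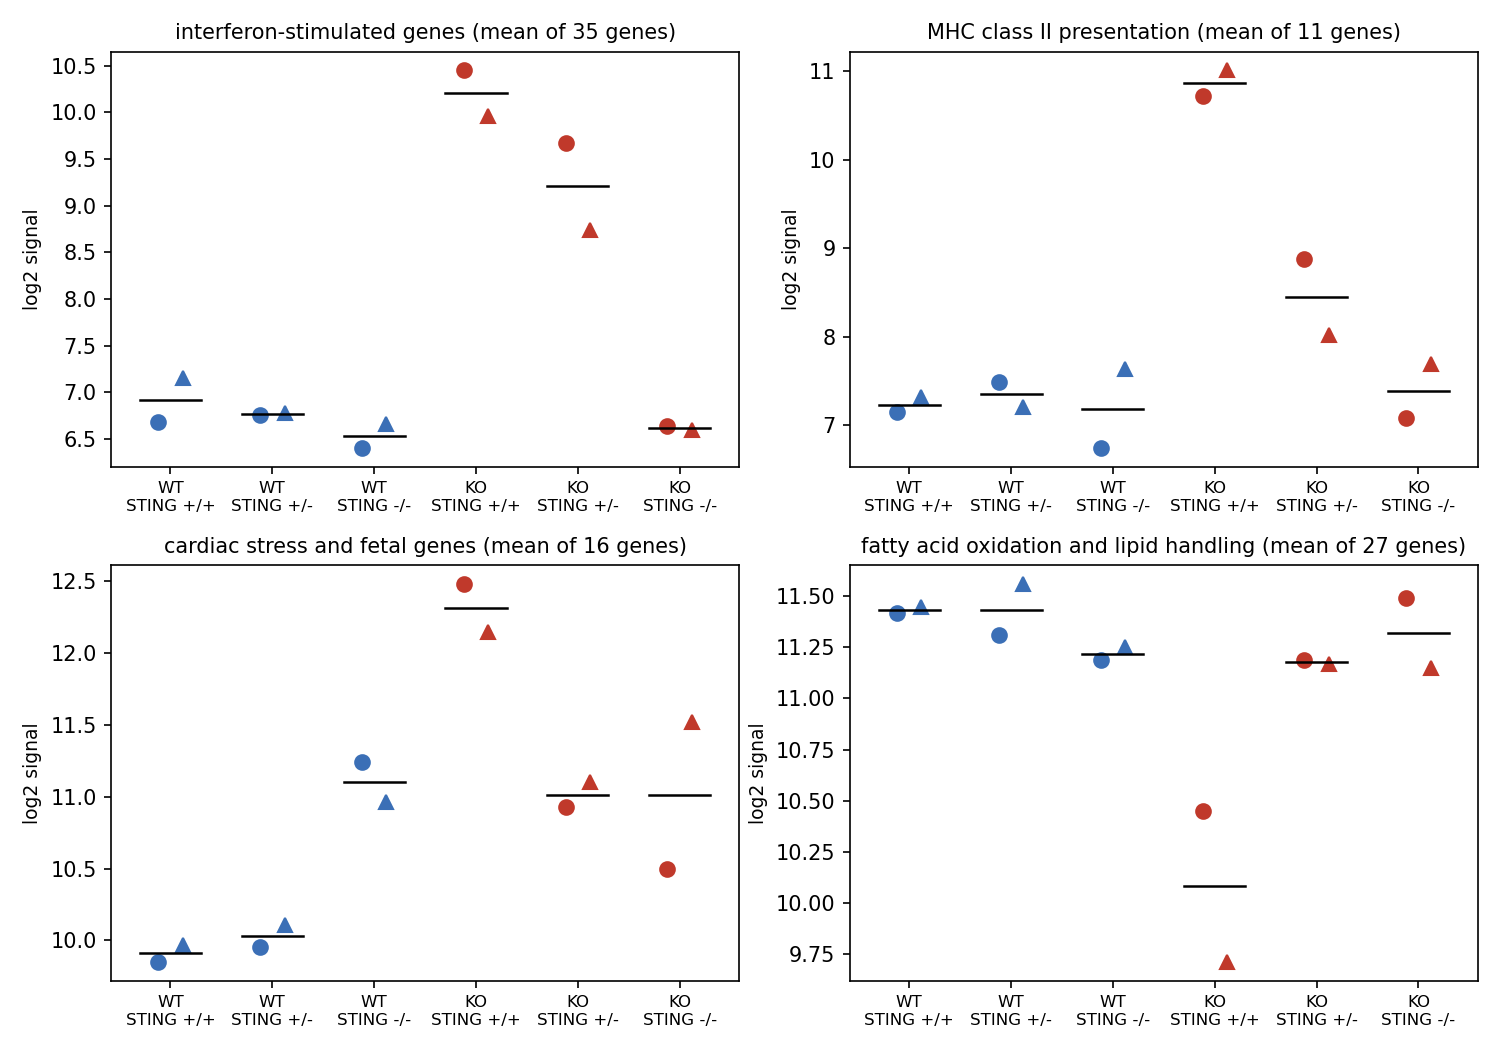
Mean normalized log2 signal of 4 gene lists per array (y axis) in the 6 genotype groups (x axis); circles are replicate 1, triangles replicate 2, bars the mean of 2 arrays, blue Trex1 WT and red Trex1 KO. The interferon-stimulated mean reads 10.45 and 9.97 on Trex1 KO, STING +/+, 9.67 and 8.74 on Trex1 KO, STING +/-, and 6.40 to 7.16 on the other 8 arrays.

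On STING +/-, hearts labelled Trex1 KO also carried raised interferon transcripts. Isg15 was 30.4-fold higher, Usp18 27.1-fold, Ifit3 26.4-fold and Irf7 21.7-fold. Apol9a was at least 27.3-fold and Plac8 at least 33.0-fold higher than a WT signal not above background. In total 197 features passed the threshold, 177 higher and 20 lower. Interferon-stimulated genes rose in 21 of 35 members (32 adjusted over the list alone) and fell in 0, with a median of 2.15 (2.19 with bounds); adjusted p = 0.0935 with an estimated correlation. The interferon-gamma-inducible GTPases rose in 8 of 13, with Igtp at 4.11 ± 0.39 and Gbp3 at 3.63 ± 0.45, and MHC class I genes in 11 of 19, with H2-Q6 at 3.55 ± 0.47 and Psmb8 at 2.87 ± 0.58. Their estimated-correlation values were adjusted p = 0.106 and adjusted p = 0.0935. Chemokines and cytokines rose in 6 of 28 and fell in 1, with Ccl5 at 4.44 ± 0.42 and Cxcl9 at 3.68 ± 0.38; adjusted p = 0.151 with an estimated correlation.

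MHC class II genes rose in 0 of 11 over all features tested and in 8 adjusted over the list alone, with a median of 1.26 (1.27 with bounds); adjusted p = 0.206 with an estimated correlation. Macrophage markers rose in 3 of 20 (10 adjusted over the list alone), with Mpeg1 at 2.51 ± 0.45; adjusted p = 0.151 with an estimated correlation. T cell and NK cell markers rose in 3 of 17, with Nkg7 at 2.50 ± 0.33, and adjusted p = 0.206 with an estimated correlation. Complement rose in 1 of 10, Cfb, and in 9 adjusted over the list alone; adjusted p = 0.151 with an estimated correlation. Cell cycle genes rose in 2 of 17 (11 adjusted over the list alone), Cdk1 by 1.99 ± 0.37 and Nusap1 by 1.58 ± 0.32, with adjusted p = 0.151 with an estimated correlation, and cell death genes in 2 of 15, Casp1 by 2.29 ± 0.31 and Mlkl by 1.62 ± 0.27, with adjusted p = 0.182. The natriuretic peptide gene Nppa was higher by 2.42 ± 0.22, the 1 rise among 16 cardiac stress genes; adjusted p = 0.106 with an estimated correlation. Of the metabolic and contractile lists, fatty acid oxidation (0 of 27 past the threshold, median -0.23, also with bounds), oxidative phosphorylation (0 of 27, median -0.20, -0.23 with bounds) and contractile genes (0 of 23, median 0.07) held no gene past limma's threshold; 1821 features had an unadjusted p under 0.05. As lists, fatty acid oxidation and oxidative phosphorylation were lower by camera (adjusted p = 0.00429 and 0.00342), with adjusted p = 0.481 and adjusted p = 0.454 with an estimated correlation. Camera also called extracellular matrix genes (1 of 31 past limma's threshold, adjusted p = 0.257 with an estimated correlation), fibroblast markers (0 of 11, adjusted p = 0.402), NF-kappaB targets (0 of 18, adjusted p = 0.206) and DNA damage genes (0 of 17, adjusted p = 0.206) higher. The atrial list, of which replicate 2 of this KO group carried a raised signal, had a median of 0.95 (1.72 with bounds; camera adjusted p = 0.317).

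The largest falls on STING +/- were led by Lrrc2, a leucine-rich repeat gene detected on 1 of the 2 KO arrays (-6.16 ± 0.56), and Epm2aip1 (-3.33 ± 0.27). Retnla (-3.29 ± 0.63), made by alternatively activated macrophages, and Bckdhb (-2.63 ± 0.28), a subunit of branched-chain keto acid dehydrogenase, followed. Of the 19 lower genes with a location in the GRCm38.p6 gene table, 8 lay on the same chromosome as Trex1, 42.1% against 5.7% of all located genes tested (one-sided Fisher's exact p = 4.64e-06). The count of 197 moved to 112 with only the 4 arrays compared, 102 without the filter on dim probes and, with 1 array left out, to 55 and 56 (WT, STING +/- replicates 1 and 2), 52 and 316 (KO, STING +/- replicates 1 and 2) and 318 (either KO, STING +/+ array). Leaving out the 2 arrays with low Hnrnpa2b1, a step added after the data were seen, gave 101.

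Across all 15561 features the effect of Trex1 loss on STING +/+ correlated with that on STING +/- (r = 0.531 across genes, which are not independent replicates). The 2 comparisons share no array. Of the 1833 features higher on STING +/+, 83.4% were also higher on STING +/-, with a median of 0.40 against 1.54 (1.41 with bounds), and 175 passed there. With 1 array left out r was as low as 0.372 (without KO, STING +/+ replicate 1) and as high as 0.646 (without KO, STING +/+ replicate 2). Of the 1545 lower features, 74% were lower on STING +/-, with a median of -0.20 against -1.13 (-1.12 with bounds), and 10 passed there.

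The difference between the effect on STING +/+ and that on STING +/- was tested directly, and 299 features passed, 217 with a higher value on STING +/+ and 82 with a lower one. The chemokines Ccl11 (3.93 ± 0.69), Ccl7 (3.87 ± 0.84) and Ccl4 (3.77 ± 0.65) and the gene Nmrk2 (4.70 ± 0.61) had the higher values. Lrrc2 (6.09 ± 0.80) was above background on 0 of the 4 STING +/+ arrays, so its fitted difference only sets the fall on STING +/- against background. The intermediate filament gene Krt18 (3.87 ± 0.32) was above background on 0 of the 4 STING +/- arrays, so its Trex1 effect there was not measured. Ephb1 (-4.60 ± 0.51), Scara5 (-3.39 ± 0.36) and Smco1 (-3.19 ± 0.34) had the lower ones. Ephb1 lies on the chromosome of Trex1, and with Trex1 intact it averaged 8.99 on STING +/+ and 7.03 on STING +/-. T cell and NK cell markers differed in 7 of 17 members and MHC class II genes in 5 of 11; adjusted p = 0.231 with an estimated correlation for each. Cd6 and Cd3e, with fitted differences of 2.94 and 2.84, were above background on 0 of the 4 WT arrays compared, and Cd6 on 1 of the 2 KO, STING +/- arrays, so these values are not exact. Interferon-stimulated genes differed in 0 of 35 over all features and in 7 adjusted over the list alone, with a median of 0.96; adjusted p = 0.447 with an estimated correlation, and 3183 features had an unadjusted p under 0.05 in limma. The count of 299 moved to 105 with array weights, 23 with only the groups compared, 194 without the filter, 110 with a stricter filter and 15 without the 2 arrays with raised atrial signal. With 1 array left out it was 21 and 41 (WT, STING +/+ replicates 1 and 2), 25 and 119 (WT, STING +/- replicates 1 and 2), 3027 (KO, STING +/+ replicate 1), 26 (KO, STING +/- replicate 2) and 118 (either WT, STING -/- array).

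On STING -/-, Trex1 loss left the interferon lists without a member past the threshold. Interferon-stimulated genes rose in 0 of 35 members, also adjusted over the list alone, with a median of 0.07 (0.08 with bounds); Ly6e differed by 0.14 and Ifi27l2a by -0.74 (adjusted p = 1 each). The medians were 0.04 for the interferon-gamma-inducible GTPases (0.08 with bounds), -0.05 for MHC class I (-0.09), 0.18 for MHC class II (0.17) and 0.05 for macrophage markers (0.05), with 0 members past the threshold in each. In total 2 features passed, both lower: Ucp1, the uncoupling protein of brown fat, at least 7.89-fold lower, and the fatty acid elongase Elovl6, by -2.03 ± 0.23 (adjusted p = 0.031). In all, 268 features had an unadjusted p under 0.05 in limma. The adipocyte list had 1 fall among 8 and a median of -1.52, and its camera call held with an estimated correlation (adjusted p = 0.0162). The WT arrays of this comparison carried the raised atrial and adipocyte transcripts described above, with adipocyte list means of 9.93 and 10.1, against 7.61 and 9.08 on the KO arrays. The atrial list had a median of -1.23, with 0 of 10 past the threshold (adjusted p = 0.799 with an estimated correlation). Camera also called extracellular matrix genes (0 of 31 past limma's threshold) and immediate early genes (0 of 18) lower, with adjusted p = 0.903 with an estimated correlation for each. Thymus markers (0 of 3, lower) had adjusted p = 0.475 and erythroid markers (0 of 4, higher) adjusted p = 0.592. Without KO, STING -/- replicate 1 camera's direction for the atrial and extracellular matrix lists turned to the other side. That for immediate early genes turned without WT, STING -/- replicate 1. The count of 2 was 44 without KO, STING -/- replicate 2, 5 without either KO, STING +/+ array, and 4 without either WT, STING +/- array or WT, STING -/- replicate 1. It was 1 without either WT, STING +/+ array, either KO, STING +/- array or KO, STING -/- replicate 1, and 27 without the 2 arrays with raised atrial signal, a step added after the data were seen.

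The features called on STING +/+ were re-measured on these arrays. Of the 1833 higher features 47.7% were higher on STING -/-, with a median of -0.01 and 0 past the threshold. Of the 1545 lower features 44.1% were lower, with a median of 0.03 and 0 past it. The correlation across all genes was -0.05. It was -0.155 without KO, STING -/- replicate 2, -0.135 without WT, STING -/- replicate 1, 0.0581 without WT, STING -/- replicate 2 and 0.143 without KO, STING -/- replicate 1.

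The difference between the effect on STING +/+ and that on STING -/- was tested directly, and 1536 features passed, 996 with a higher and 540 with a lower value on STING +/+. Plac8 (7.42 ± 0.78), Ccl4 (6.93 ± 0.65), Lgals3 (6.91 ± 1.39) and Ccl5 (6.70 ± 0.59) had the higher values, and Ephb1 (-4.82 ± 0.51), Ces1d (-4.23 ± 0.43), Timp4 (-4.09 ± 0.74) and the Z-disc gene Myot (-4.09 ± 0.68) the lower ones. Ephb1 lies on the chromosome of Trex1, and with Trex1 intact it averaged 8.99 on STING +/+ and 6.19 on STING -/-. Interferon-stimulated genes differed in 29 of 35 members, with Usp18 at 6.20, and adjusted p = 0.14 with an estimated correlation. Fatty acid oxidation genes differed in 11 of 27, with Acot1 at -3.13 and Hadh at -2.88, and adjusted p = 0.143 with an estimated correlation; T cell and NK cell markers differed in 12 of 17, and adjusted p = 0.14 with an estimated correlation. Cd3d, at a fitted 5.09, was above background only on the KO, STING +/+ arrays among the 8 compared, so no Trex1 effect was measured for it on STING -/-. With 1 array left out the count of 1536 moved to 688 and 783 (WT, STING +/+ replicates 1 and 2), 3392 (KO, STING +/+ replicate 1), 849 and 740 (WT, STING -/- replicates 1 and 2) and 651 (KO, STING -/- replicate 1). It moved to 841 with Myl7, an atrial light chain, as a covariate added after the data were seen.

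**Figure D3:**
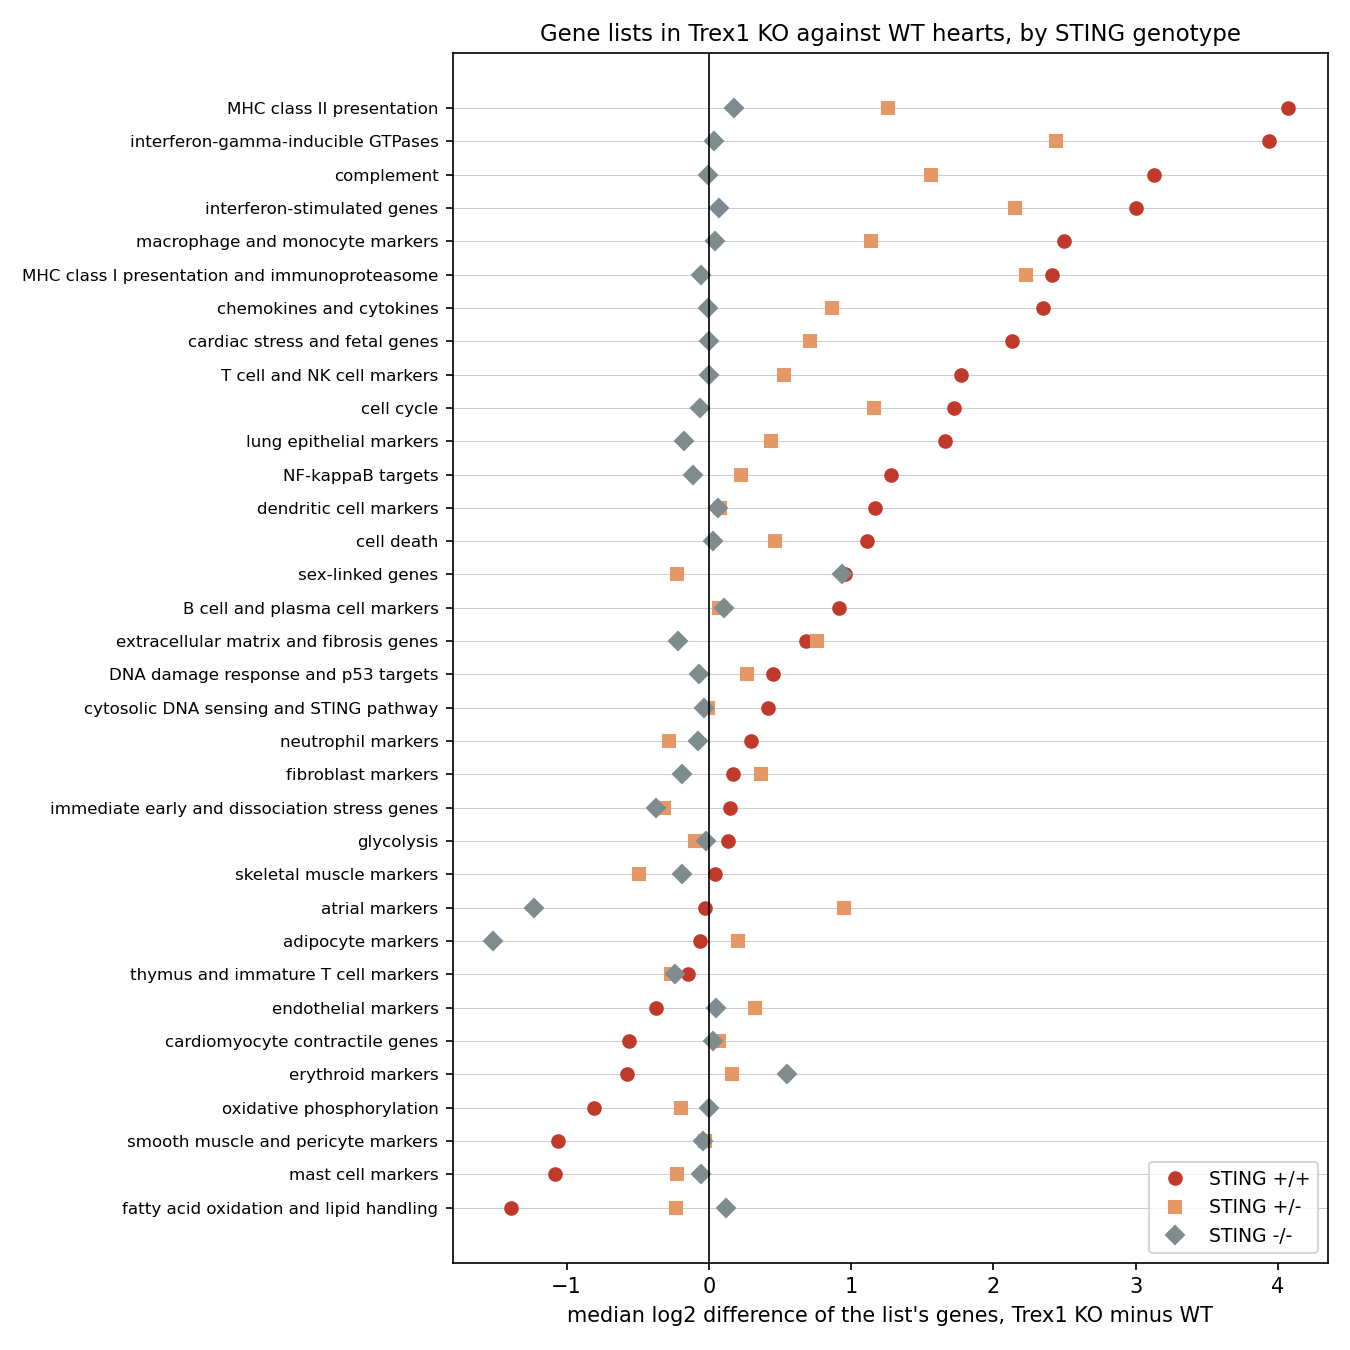
Median log2 difference (x axis) between Trex1 KO and WT over the members of each of the 34 gene lists (y axis), on STING +/+ (circles), +/- (squares) and -/- (diamonds). The median of the interferon-stimulated list is 3.00 on STING +/+, 2.15 on STING +/- and 0.07 on STING -/-.

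Averaged over STING +/+ and +/-, 2691 features passed in Trex1 KO against WT, 1500 higher and 1191 lower. Plac8 (6.44 ± 0.39), Ccl5 (5.45 ± 0.29), Usp18 (5.43 ± 0.26) and Isg15 (5.37 ± 0.35) led the rises, with Apol9a at least 40.5-fold higher. Retnla (-3.27 ± 0.45), Ces1d (-2.76 ± 0.21) and the splicing regulator Rbfox1 (-1.94 ± 0.15) were among the largest falls. Interferon-stimulated genes rose in 34 of 35; adjusted p = 0.0929 with an estimated correlation. Fatty acid oxidation genes fell in 15 of 27, and adjusted p = 0.146 with an estimated correlation. The count was 1688 and 1720 without WT, STING +/+ replicates 1 and 2, and 1569 without KO, STING +/- replicate 1.

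Among hearts labelled Trex1 KO, those with STING -/- were lower than those with STING +/+ in 33 of 35 interferon-stimulated genes and higher in 17 of 27 fatty acid oxidation genes. With an estimated correlation these lists had adjusted p = 0.135 and adjusted p = 0.171. Usp18 was 94.4-fold lower in STING -/- than in STING +/+, Irf7 99.2-fold, Ccl5 144-fold and Cxcl9 110-fold lower, and Ccl4 at least 129-fold lower. Irf7 and Ccl5 were above background on only 1 of the 2 STING -/- arrays, so their folds are not exact. Inmt, an amine methyltransferase, was 104-fold higher, and Gsn, Ces1d and Timp4 were higher by 5.46 ± 1.24, 4.68 ± 0.30 and 4.49 ± 0.52. In total 3727 features passed, 1752 higher and 1975 lower. Interferon-stimulated genes fell in 33 of 35 members, with a median of -3.37 (-3.24 with bounds); adjusted p = 0.135 with an estimated correlation. MHC class II genes fell in 10 of 11, T cell and NK cell markers in 12 of 17 and cell cycle genes in 16 of 17, with adjusted p = 0.159, 0.135 and 0.167 with an estimated correlation. Fatty acid oxidation genes rose in 17 of 27, Acot1 by 3.17 ± 0.37 and Ppara by 2.31 ± 0.34, and adjusted p = 0.171 with an estimated correlation. Oxidative phosphorylation genes rose in 12 of 27, with Sdhc at 1.13 ± 0.23, and adjusted p = 0.216. The atrial list, raised on replicate 2 of the STING -/- group, had 3 rises among 10; adjusted p = 0.385 with an estimated correlation. This comparison shares the Trex1 KO, STING +/+ arrays with the first one, so their values are not independent. The count of 3727 moved to 1925 with array weights, 1288 with only the groups compared, 2021 without the 2 arrays with raised atrial signal and 2134 and 2335 without KO, STING -/- replicates 1 and 2.

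In Trex1 WT hearts, 9 features passed between STING -/- and +/+, 6 higher and 3 lower (66.7% higher, against 80% of 10 with quantile normalization or the authors' processed values), and 1459 had an unadjusted p under 0.05 in limma. Lrrc2 was at least 71.3-fold higher, Epm2aip1 higher by 4.29 ± 0.26, and the stearoyl-CoA desaturase Scd1 by 4.32 ± 0.56. Lrrc2 and Epm2aip1 lie on the chromosome of Trex1, which held 6 of the 50 located genes with an unadjusted p under 0.001 (one-sided Fisher's exact p = 0.0636). Ucp1 was at least 7.63-fold and Elovl6 at least 3.86-fold higher, and Nppa was higher by 1.61 ± 0.22. Cdh2, N-cadherin, was at least 8.42-fold lower and Ephb1, an ephrin receptor gene also on the chromosome of Trex1, fell by 2.80 ± 0.36. Cdh2 lies on the chromosome of Sting1, which held 3 of the 50 located genes (one-sided Fisher's exact p = 0.123). It read 4.30 to 4.46 on the STING -/- arrays of either Trex1 state. The ninth feature has no gene name here. Adipocyte markers rose in 2 of 8 (6 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 0.0357). Atrial markers rose in 1 of 10 (8 adjusted over the list alone), with a median of 3.12 (2.85 with bounds); adjusted p = 0.434 with an estimated correlation. Both STING -/- arrays carried the raised atrial and adipocyte signals. Interferon-stimulated genes were past the threshold in 0 of 35, with a median of -0.37; adjusted p = 0.817 with an estimated correlation. Camera also called cardiac stress genes (1 of 16 past limma's threshold) and extracellular matrix genes (0 of 31) higher, with adjusted p = 0.434 and 0.817 with an estimated correlation. Oxidative phosphorylation (0 of 27), fatty acid oxidation (0 of 27) and glycolysis (0 of 15) were called lower, with adjusted p = 0.817 for each. With Myl7 as a covariate, added after the data were seen, camera's direction turned for extracellular matrix (camera adjusted p = 0.675) and fatty acid oxidation (0.749). The count of 9 moved to 166 with array weights, 141 with only the groups compared and 2 with Myl7 as a covariate. It was 135 without either KO, STING -/- array, 3 without WT, STING +/+ replicate 1, 14 without either KO, STING +/+ array and 5 without either KO, STING +/- array.

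Between STING +/- and +/+ in Trex1 WT hearts 2 features passed, both higher: Lrrc2, at least 103-fold, and Epm2aip1, by 3.54 ± 0.27 (adjusted p = 0.0015 each). Both lie on the chromosome of Trex1, which held 7 of the 13 located genes with an unadjusted p under 0.001 (one-sided Fisher's exact p = 2.42e-06), against 1 of 13 on that of Sting1 (p = 0.275). Unadjusted p was under 0.05 for 541 features in limma. Interferon-stimulated genes had 0 of 35 past the threshold and a median of -0.16 (-0.21 with bounds; camera adjusted p = 0.225). Extracellular matrix genes had 0 of 31 past it and a median of -0.47 (-0.52 with bounds), and their camera call was lost with an estimated correlation (adjusted p = 0.726). The same held for fibroblast markers (0 of 11) and smooth muscle markers (0 of 11), also lower (adjusted p = 0.726 each), for mast cell markers (0 of 6, lower, adjusted p = 0.662) and for sex-linked genes (0 of 4, higher, adjusted p = 0.662). Xist was present on both STING +/+ arrays and on 0 of the 2 STING +/- arrays, and with Xist as a covariate, added after the data were seen, 0 features passed in limma and 984 had an unadjusted p under 0.05. Sex and STING genotype are fully confounded between these groups, so the covariate cannot separate them. With only the 4 arrays compared, 7 features passed; 16 passed without WT, STING +/+ replicate 2, 6 without WT, STING +/- replicate 2 and 4 without either KO, STING +/+ array.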

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

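The tests of the atrial, metabolic and chromosome patterns were chosen only after the results were seen; the test over splits of the arrays was planned. The wording of the dilution explanation was changed, and its endothelial comparison added, after a first result had favoured dilution. The tests given for atrial and adipose tissue and for the Trex1 chromosome replaced earlier ones, and that of loss of Trex1 more than once, when their values had been seen.

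The effect of Trex1 loss differed between STING +/+ and STING -/- by a test of the difference itself (limma, adjusted) for 1536 features. In log2 units the difference was 7.42 for Plac8, 6.93 for Ccl4, 6.91 for Lgals3, 6.72 for Apol9a, 6.70 for Ccl5, 6.67 for Cd72, 6.66 for Fcgr4, 6.63 for Me1, 6.43 for Ch25h and 6.34 for C2. It was -4.82 for Ephb1, -4.53 for Cd163, -4.23 for Ces1d, -4.09 for Timp4, -4.09 for Myot, -4.02 for Smco1, -3.96 for Gpcpd1, -3.81 for Scara5, -3.78 for Aqp1 and -3.55 for Kcnv2. Ephb1 lies on the chromosome of Trex1. Values of genes below background in a group are fitted differences and no bounds; Apol9a was above it on 0 of the 4 STING -/- arrays.

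Gene lists were taken as different in this comparison where camera with the preset correlation and fry both gave an adjusted p under 0.05. Their median log2 differences were 2.87 for interferon-stimulated genes, 3.82 for interferon-gamma-inducible GTPases, 2.58 for MHC class I, 3.83 for MHC class II, 2.72 for chemokines and cytokines, 0.555 for cytosolic DNA sensing, 1.35 for NF-kappaB targets and 3.08 for complement. For markers they were 2.64 for macrophages, 1.62 for T and NK cells, 0.905 for B cells, 0.856 for dendritic cells and 1.62 for adipocytes. The adipocyte value sets a median Trex1 effect of -0.06 on STING +/+ against -1.52 on STING -/-, where both WT arrays stood apart with adipocyte means of 9.93 and 10.1. Cardiac stress genes gave 1.89, cell cycle 1.81, cell death 1.29, contractile genes -0.429, oxidative phosphorylation -0.915 and fatty acid oxidation -1.34. With an estimated correlation 0 of these 19 list differences passed camera's threshold (adjusted p from 0.102 to 0.203), and limma had 3855 features with an unadjusted p under 0.05.

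The effect differed between STING +/+ and STING +/- by the same kind of test for 299 features. The difference was 6.09 for Lrrc2, 4.70 for Nmrk2, 3.93 for Ccl11, 3.87 for Ccl7, 3.87 for Krt18, 3.77 for Ccl4, 3.73 for Sprr1a, 3.43 for Ccl3, 3.43 for Serpina3f and 3.41 for Acod1. It was -4.60 for Ephb1, -3.39 for Scara5, -3.19 for Smco1, -3.17 for F13a1, -3.16 for Ces1d, -3.16 for Pdp2, -3.05 for Kcnip2, -2.95 for Cdkn1c, -2.89 for Aqp1 and -2.77 for Fign. No Trex1 effect was measured for Lrrc2 on STING +/+ or for Krt18 on STING +/-, since 0 of the 4 arrays there were above background. Lrrc2 and Ephb1 lie on the chromosome of Trex1. For lists past the threshold both by camera with the preset correlation and by fry, median differences were 2.79 for MHC class II, 1.69 for chemokines and cytokines, 0.533 for cytosolic DNA sensing, 1.16 for NF-kappaB targets, 1.92 for T and NK cells, 0.889 for neutrophils and 1.05 for dendritic cells. They were -0.509 for contractile genes, 1.40 for cardiac stress genes, -0.548 for endothelial markers, -0.464 for oxidative phosphorylation and -0.949 for fatty acid oxidation. With an estimated correlation 0 of these 12 passed (adjusted p from 0.231 to 0.312), and limma had 3183 features with an unadjusted p under 0.05.

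Of the 35 splits of the 8 STING +/+ and +/- arrays into 4 and 4, 1 gave as many genes as the split by Trex1, the real one itself. A limma fit of these 2 groups called 566 genes in it and at most 2 in any other. With 35 splits the real one can at best be 1 of 35, so a random division of these arrays is made unlikely but not excluded. The splits also treat the arrays as exchangeable, although both WT, STING +/+ arrays carried Xist and both WT, STING +/- arrays did not.

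Atrial and adipose transcripts were raised on 3 of the 4 STING -/- arrays. The 2 Trex1 KO, STING -/- arrays differed by 4.78 in the mean of the atrial list, 1 of the 4 lay at the STING +/+ level and 1 STING-carrying array lay over 1 log2 above it. These readings argue against loss of STING as the only cause. They rest on 1 array on each side and on the list by which the arrays were noticed, so they are no separate test. Atrial and adipose tissue in the sample stays open. The 3 arrays stood out by the atrial list itself, so that list is no test of it; of the adipocyte list 4 of 8 members (50%) were higher on each of the 3 than on every STING +/+ array, and the median contractile gene differed by 0.0061. Nppa is also a cardiac stress gene and Lpl, an adipocyte marker, a lipid handling gene.

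Fatty acid oxidation genes fell in 18 of 27 members in hearts labelled Trex1 KO, STING +/+, and oxidative phosphorylation genes in 16 of 27. Without the 2 arrays with a low Hnrnpa2b1 signal, which leaves 1 array of that group, the median fatty acid oxidation difference was -1.06. The fall was thus not confined to the array left out. That a low Hnrnpa2b1 signal marks poor RNA quality was not shown, so RNA quality as a cause was not tested directly. The 1 array left lacked Xist, which both WT, STING +/+ arrays carried, so sex and Trex1 are confounded there. Replicate 2, which carried Xist as they did, gave -1.59. Dilution of heart muscle RNA by RNA of other cells stays open. Metabolic genes had a median of -1.09 and contractile genes of the same brightness -1.14, a difference of 0.0453 (permutation p = 0.707 over genes). Without those 2 arrays the medians were -1 and -0.877, a difference of -0.126. The whole contractile list had a median of -0.235 without those 2 arrays. The endothelial median over all arrays was -0.37, 0.72 above the metabolic one (permutation p = 0.00027). Neither was matched on brightness, and endothelial genes need not fall with those of heart muscle, so these values do not decide on dilution. A response to loss of Trex1, the biological explanation in the design, was not tested apart from these or from sex.

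Genes of the Trex1 chromosome made up 8 of the 19 located falls in Trex1 KO on STING +/-. They were 5 of the 147 located rises there (one-sided Fisher's exact p = 0.928) and 84 of the 1234 located falls on STING +/+ (p = 0.0473). At an unadjusted p under 0.001 they were 4 of 10 located genes on STING -/-, which shares no array with the STING +/- comparison (one-sided Fisher's exact p = 0.00167), and with Trex1 intact 7 of 13 between STING +/- and +/+ (p = 2.42e-06, sharing the WT, STING +/- arrays) and 6 of 50 between STING -/- and +/+ (p = 0.0636). With Trex1 intact all 8 genes of the falls on STING +/- read lower on STING +/+ than on STING -/- arrays, none of which picked them, with a median of -0.783 (95% bootstrap interval over genes -4.29 to -0.528). The interval measures spread among genes of the same chromosome, which are not independent, and not spread among mice. That all 8 differed with Trex1 intact argues against loss of Trex1 as the only cause of the low values, although both STING -/- arrays carried the raised atrial signal. These genes lay 51 to 236 protein-coding genes from Trex1. Lrrc2 averaged 4.64 in WT, STING +/+, below background, 11.16 in WT, STING -/- and 10.63 in KO, STING -/-. Epm2aip1 averaged 5.01, 9.30 and 8.35 in these groups. DNA of another strain around Trex1, in a mixed background, may account for part of the pattern. A segment that goes with the Trex1 genotype in every group does not account for Lrrc2 and Epm2aip1, the nearest to Trex1 of these genes. Both were high in KO, STING -/- and low in WT, STING +/+, which the remaining genes did not show. An added effect of loss of Trex1 stays open, since all 8 were lower in KO on STING -/- (median -1.12). On STING +/+ the median was -0.113, with 5 of the 8 near background in WT.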

How the results depend on the processing

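Leaving out 2 arrays with a low Hnrnpa2b1 signal or 2 with raised atrial signal, and the Myl7 and Xist covariates, were chosen after the data were seen; the other alternatives were planned. Of 874 results for named genes, 561 of them past the threshold, 1 turned direction in 1 setting: Rcan1, in the difference between STING +/+ and +/-, at -0.06294 (adjusted p = 0.989) with the largest-variance probe. Between 9 (variance trend) and 139 (only the groups compared) lost the threshold under the planned settings other than leaving out 1 array, 12 to 130 with 1 array left out and 45 to 104 under the added settings; 52 were not tested with the stricter filter. The variance trend moved no count past 1.5 times. Trex1 KO against WT on STING -/-, with 2 features past the threshold, had 1 with quantile normalization, 1 with the authors' processed values, 1 without the filter, 0 with the stricter filter (limma; 181 at an unadjusted p under 0.05), 4 with only the groups compared, 8 without the low-Hnrnpa2b1 arrays, 27 without the atrial arrays, 1 with Myl7 and 1 with Xist. On STING +/- 197 became 102 without the filter, 112 with only the groups compared and 101 without the low-Hnrnpa2b1 arrays. On STING +/+ 3378 became 1998 with array weights and 1418 with only the groups compared, where 67.6% of calls were higher against 54.3%. STING -/- against +/+ on Trex1 KO went from 3727 to 1925, 1288 and, without the atrial arrays, 2021. On Trex1 WT 9 became 166 with array weights, 141 with only the groups compared, 15 without the low-Hnrnpa2b1 arrays, 105 without the atrial arrays, 2 with Myl7 and 5 with Xist; quantile normalization and the authors' processed values gave 80% higher calls against 66.7%. STING +/- against +/+ on Trex1 WT went from 2 to 7 with only the groups compared and 0 with Xist (limma; 984 unadjusted). The difference between STING +/+ and -/- went from 1536 to 841 with Myl7. That between STING +/+ and +/- went from 299 to 194 without the filter, 110 with the stricter one, 105 with array weights, 23 with only the groups compared, 71 without the low-Hnrnpa2b1 arrays, 15 without the atrial arrays and 126 with Myl7. Of 141 gene list results 2 remained with an estimated correlation. With 2 arrays and 1 fitted mean per group, array weights are equal within a group by construction, so they could not tell 1 array of a group from the other. They ran from 0.339 for Trex1 KO, STING +/+ to 1.76 for Trex1 WT, STING +/+. Fits of only the groups compared have fewer residual degrees of freedom; otherwise the cause was not tested.

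With 1 array left out, the counts ranged from 1659 to 5168 (Trex1 KO against WT on STING +/+), 52 to 318 (+/-), 1 to 44 (-/-) and 1569 to 3895 (averaged). They ranged from 2134 to 5456 (STING -/- against +/+ on Trex1 KO), 3 to 135 (on Trex1 WT), 2 to 16 (STING +/- against +/+), 651 to 3392 (difference from STING -/-) and 21 to 3027 (difference from STING +/-). The lone array of a group was then assumed to vary like the other groups. Camera's direction turned for some gene lists when 1 array was left out, and their adjusted p then ranged as follows. For immediate early genes it was 1.32e-06 to 0.988 (STING +/- against +/+ on Trex1 WT), 5.17e-07 to 0.909 (Trex1 KO against WT on STING +/-) and 5.54e-13 to 0.555 (on STING -/-). On STING -/- it was also 0.00155 to 0.652 for complement, 0.0165 to 0.993 for cardiac stress genes, 2.78e-09 to 0.189 for extracellular matrix and 6.6e-20 to 0.163 for atrial markers. The turns came without WT, STING +/- replicate 1 (1.32e-06), WT, STING +/- replicate 2 (0.0476), WT, STING -/- replicate 1 (0.555) and KO, STING -/- replicate 1 (complement 0.0165, extracellular matrix 0.189, atrial 0.163) or replicate 2 (cardiac stress 0.0424). Direction also turned for immediate early genes without the low-Hnrnpa2b1 arrays (7.8e-05), cardiac stress genes without the atrial arrays (0.0147), extracellular matrix (0.675) and fatty acid oxidation (0.749) with Myl7, and fatty acid oxidation with Xist (0.0429). The cause was not tested. A slide block was not run. No paired analysis was possible because the sample numbers in the titles are unique to each sample. Probes near background understate folds, which limits what these arrays show for dim genes.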

Other observations

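The values here were looked up only after the data were seen. Mup2, a major urinary protein gene, read 10.6 on replicate 2 of Trex1 WT, STING +/-, 8.27 on replicate 2 of Trex1 KO, STING +/+, 12.5 and 7.82 on the Trex1 KO, STING +/- arrays and 9.92 on replicate 2 of Trex1 WT, STING -/-. Replicate 2 minus 1 of Trex1 KO, STING +/+ correlated with replicate 1 minus 2 of Trex1 WT, STING +/- across 15561 features (r = 0.455; genes are not independent replicates), the pair of arrays with the low Hnrnpa2b1 signals.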
